A study of Mus musculus with 12 samples.

How the data were processed

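Poly(A) RNA was sequenced from muscle labelled soleus or quadriceps of C57BL/6N mice aged 3 months, wild type or PTRF knockout. Per the labels' protocols, total RNA was isolated with TRIzol and libraries were made with a NEBNext Ultra kit. STAR 2.5.3a, kallisto 0.43.0 and the builds GRCm38 and mm10 are named in the submitters' processing notes, without the step each was used for. The deposited values were taken as TPM (length-normalised shares of the transcripts of a library) from the values alone: they are fractional and sum to 843194 to 872482 in each library, and no label or file header names the unit. If they were in another length-scaled unit, levels and fold changes between libraries would carry a different library factor. TPM keeps no read depth, so neither depth nor a counting interval is given. TPM is a share, so a change in a few abundant transcripts, here those of the mitochondrial genome, moves the values of all other genes.

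All 12 samples were grouped by the labels. The 6 pairs of samples with the same genotype and number in both muscles held equal values for every gene above 0, with a largest difference of 0 TPM. The soleus wild-type sample 3 also listed 5815 genes at 0 that its counterpart left out. The pairs were counted as 6 libraries. Genes missing from a sample were set to 0 over the 21936 genes listed anywhere. Of the gene identifiers, 21817 (99.5%) were found in GENCODE release 21 for mouse, 21780 of them as protein coding, and 36 symbols were repeated. Positions come from that annotation. Genes with near-identical copies, such as haemoglobin and class I genes, may have had their reads divided in ways the sources used here do not state.

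Before the data were examined, the tests, the alternatives, 29 gene lists and the rule for named genes were fixed. The test fixed for values of this kind was used. Genes with at least 1 TPM in at least 3 libraries (11056) were tested on log2(TPM + 1) with limma 3.58.1 in R 4.3.3 with an intensity trend and Benjamini-Hochberg adjustment at 0.05, on 4 residual degrees of freedom. Fold changes are on the log2(TPM + 1) scale, which understates changes of low genes. Lists with at least 5 measured members (28) were tested with camera, two-sided, with a preset correlation of 0.01 and again with an estimated correlation. Both labelled knockout comparisons were this one fit. The interaction of genotype with muscle and the comparison of muscles in wild type were not run, because their samples are copies. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

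The named genes were Cavin1, the 10 genes up and 10 down with the largest log2 fold change among those passing, with groups that do not overlap, a mean of at least 5 TPM in the higher group and a proper symbol, and from each list the 4 passing members with the smallest adjusted p, or the member with the highest mean where none passed. Myh7, Myh4, Tnnt1 and Tnnt3 were fixed for the muscle comparison. A gene that the rule named from the cholesterol list is not reported here. Alternatives were limma without the trend, quantile normalization, trimmed-mean rescaling (30% of ratios and 5% of levels trimmed), no filter, a filter of 10 TPM, pseudocounts of 0.1 and 5, the replicate number as a block, an absolute log2 fold change of at least 1, and each library left out. A scale over nuclear genes alone, and leaving out wild-type library 2 and knockout library 1 together, were chosen after seeing the data, as were lists of clock genes and of liver genes. The test was run on simulated data for the knockout comparison with 200 of 11056 genes changed. It recovered 84% of the 100 genes changed by a log2 of 1 and 100% of the 100 changed by 2, and 8 unchanged genes were called (4.17% of calls). The simulated noise was independent between genes and held no shift of library scale. Genes were changed equally in both directions and picked from those of higher value. These rates need not hold for the real comparison, where many more genes passed and most were higher.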

Results

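The series measured polyadenylated RNA in skeletal muscle of mice with and without PTRF, the caveolar coat protein now named cavin 1 and encoded by Cavin1, with libraries labelled soleus or quadriceps and normal or knockout at 3 months of age. The labels list 12 samples, 3 per muscle and genotype. Each soleus sample held exactly the same values as the quadriceps sample of the same genotype and number, for every gene above 0, so the 12 samples were 6 distinct libraries, 3 wild type and 3 knockout, each counted as 1 sample. The muscle these 6 libraries came from is unknown, the knockout comparisons labelled soleus and quadriceps are a single comparison, and no difference between muscles was tested. The values were read as TPM, the share of each gene in the transcripts of a library after division by transcript length. Their totals ran from 843194 to 872482 TPM per library, and the sequencing depth behind them is unknown. Transcripts of the mitochondrial genome took 48.8 ± 5.05% of the TPM in wild-type libraries and 42.3 ± 3.33% in knockout libraries (SD, n = 3 each), a difference that did not pass (exact permutation test, two-sided p = 0.2, where 3 against 3 allows 0.1 at the least). Genes at 1 TPM or more numbered 10227 to 10509 in the wild-type libraries and 11148 to 11298 in the knockout libraries. The labels do not say that the numbered samples came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

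The first question was whether the labelled knockout libraries lacked the targeted transcript. Cavin1 (ENSMUSG00000004044, a protein-coding gene on the minus strand of chromosome 11 from 100956733 to 100970887 in GRCm38) stood at 45.2, 40.0 and 42.2 TPM in wild-type libraries 1, 2 and 3 and at 0.284, 0.0905 and 0.0254 TPM in knockout libraries 1, 2 and 3. The knockout mean, 0.133 ± 0.134 TPM (SD, n = 3), was 0.314% of the wild-type mean of 42.4 ± 2.63 TPM (n = 3). The log2 fold change was -5.27 with a standard error of 0.15 (limma, adjusted p = 3.1e-09). An exact permutation test of the 6 values gave p = 0.1, the smallest that 3 against 3 allows. Among the 13 measured genes of the fixed list of caveola coat and caveola-associated proteins, 9 were higher in the knockout, Cavin1 was lower and 3 did not pass (11 higher and 1 lower when adjusted over the list alone). Cav1, the main caveolin of non-muscle caveolae, rose from 81.0 ± 8.68 to 196 ± 21.01 TPM, Cavin3 from 4.20 ± 0.377 to 16.0 ± 2.04 TPM, and Ehd2, an ATPase at the caveolar neck, from 11.5 ± 1.04 to 28.1 ± 2.30 TPM. The list as a whole did not pass the camera test (adjusted p = 0.064 with the preset correlation, adjusted p = 0.72 with an estimated correlation), and after trimmed-mean rescaling of the libraries 7 members were higher and 1 lower. With the preset correlation the caveola list passed as higher after quantile normalization (0.0018), after trimmed-mean rescaling (0.0295), with no filter (0.0128), with the 10 TPM filter (0.0417), with a pseudocount of 5 (0.0246), on the nuclear-only scale (0.0488), without wild-type library 1 (0.00108), without wild-type library 2 (0.00133), without wild-type library 3 (0.000898), without knockout library 1 (0.0253) and without both wild-type library 2 and knockout library 1 (0.000427), by adjusted p, which ran from 0.000427 to 0.105 over the alternatives. None of these passed with an estimated correlation (adjusted p = 0.224 to adjusted p = 0.721). Leaving out a wild-type library also takes Cavin1 out of the tested members.

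**Figure D1:**
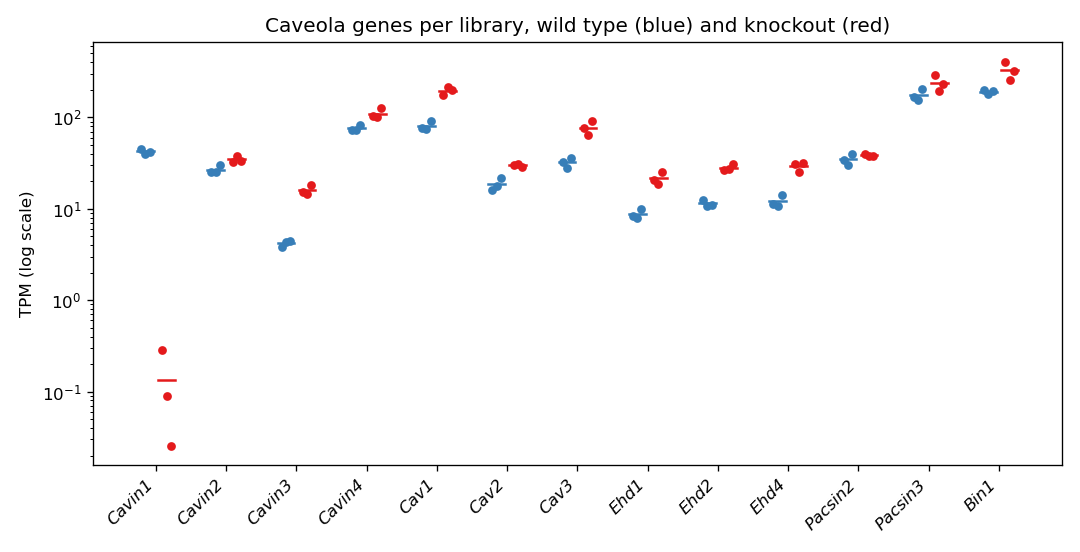
TPM on a log axis of the 13 measured caveola genes, with 1 point per library (3 wild type in blue, 3 knockout in red) and a short line at each group's mean. Cavin1 fell from a mean of 42.4 to 0.133 TPM, while Cav1, Cavin3 and Ehd2 lay higher in every knockout library.

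The next question was how widely the transcriptome differed between knockout and wild type. Of 11056 genes tested with limma, 4339 passed an adjusted p of 0.05, 4016 higher and 323 lower in the knockout. Values of the groups did not overlap for 5921 genes, 53.6% of those tested, where chance gives 10% for a single gene. Genes share the scale of their library, so a shift of scale alone can separate many genes at once. The count was made on the deposited scale only. The split by direction depended on the scale of the values. On the deposited scale 92.6% of the passing genes were higher, and the median log2 fold change of all genes was 0.33. After trimmed-mean rescaling, which moved that median to 0.02, 1717 genes were higher and 1302 lower (56.9% higher), and after quantile normalization 1373 were higher and 1450 lower (48.6% higher). On the nuclear-only scale 2850 were higher and 777 lower (78.6% higher). Of the genes called on the deposited scale, 1717 higher and 322 lower ones kept their call after trimmed-mean rescaling, and none was called in the opposite direction. Without wild-type library 2 the number of passing genes was 2784, without knockout library 1 it was 2648 and without knockout library 3 it was 2724. Counts of list members are therefore given on the deposited scale and, where they differ, after trimmed-mean rescaling. They are to be read against all tested genes, of which 4016 of 11056 were higher and 323 lower on the deposited scale. After trimmed-mean rescaling 1717 of 10992 were higher and 1302 lower.

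The order of the 10 genes that the naming rule picked for the largest increases on the log2(TPM + 1) scale depended on the pseudocount, the scale and the libraries used. Ifi27l2a rose from 16.4 ± 2.64 to 200 ± 49.0 TPM (log2 fold change 3.51 on the TPM + 1 scale), Ifit3 by 3.45, Oasl2 by 3.22 and Ifi27l2b by 3.18. The chemokine Cxcl16 rose by 3.30 and the galectin Lgals3, abundant in macrophages, by 3.16. The chemokine Ccl8 was listed at 0, 0 and 0.177 TPM in wild-type libraries and at 19.0, 8.78 and 6.24 TPM in knockout libraries. S100a5 was at 0, 0 and 0.254 TPM against 30.9, 9.60 and 16.4 TPM. Ahnak2 rose from 1.95 ± 0.313 to 40.6 ± 12.4 TPM. Myh4, the myosin heavy chain of type 2B fibres, had a log2 fold change of 4.22 (SE 1.01, limma adjusted p = 0.0075). It stood at 6.43, 193.5 and 4.21 TPM in wild-type libraries and at 238, 580.1 and 346 TPM in knockout libraries. It no longer passed when genes of low value were kept in the test (adjusted p = 0.067). Under the other alternatives it passed, but close to the threshold after trimmed-mean rescaling (adjusted p = 0.04995) and quantile normalization (adjusted p = 0.0457). The range over all alternatives was 4.39e-07 to 0.067. The Myh4 log2 fold change ran from 3.26 without wild-type library 3 to 5.87 without wild-type library 2 and 6.17 without both wild-type library 2 and knockout library 1. Wild-type library 2 held the most Myh4 of its group and knockout library 1 the least of its own, so leaving them out raises the change.

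Among the genes that the naming rule picked for the largest decreases, Pdk4, the kinase that restrains pyruvate dehydrogenase, fell from 1052 ± 160.1 to 250.5 ± 139.6 TPM (log2 fold change -2.24, SE 0.36, adjusted p = 0.00071). The mitochondrial carrier Ucp3 fell from 43.6 ± 12.999 to 10.96 ± 9.66 TPM and the acyl-CoA thioesterase Acot2 from 40.5 ± 6.25 to 8.76 ± 1.99 TPM. Carbonic anhydrase 4, Car4, fell from 10.2 ± 2.34 to 1.47 ± 0.454 TPM. The remaining genes of this set were Lrrc52 (log2 fold change -2.59), Tmem171 (-2.27), Pcp4l1 (-2.24), Dkk2 (-2.22), a secreted regulator of Wnt signalling, and Gbp6 (-1.97), a guanylate-binding protein.

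Immune genes were higher in the knockout in every list with enough members. All 22 genes for the interferon response and antigen presentation were higher, with a median log2 fold change of 2.07, and all 22 stayed higher after trimmed-mean rescaling. Irf7, a transcription factor of the interferon response, rose from 1.28 ± 0.298 to 16.2 ± 3.685 TPM, and the class I gene H2-D1 from 23.4 ± 0.717 to 102 ± 8.48 TPM. All 19 measured macrophage and monocyte genes were higher (median 1.90), and 18 of 18 after trimmed-mean rescaling. Ctss rose from 2.42 ± 0.325 to 18.01 ± 0.481 TPM, Tyrobp from 1.82 ± 0.308 to 12.3 ± 0.551 TPM and the complement gene C1qa from 3.68 ± 0.136 to 28.0 ± 6.64 TPM. Of 15 neutrophil and mast cell genes 7 were measured, and all 7 were higher (6 after trimmed-mean rescaling). Those named by the rule, Tpsb2, Cma1, Mcpt4 and Cpa3, are mast cell genes. Cpa3, and Ptprc below, were under 1 TPM in every wild-type library and met the filter through the knockout libraries alone. The same held for Cxcl16, S100a5, Ccl8 and Ifi27l2b above, and for Timp1 and Runx1 below. Being higher was thus a condition for testing such genes. Mcpt4 lost its call after quantile normalization (0.0527), by adjusted p, which ran from 3.49e-05 to 0.0527 over the alternatives. Cpa3 lost its call after quantile normalization (0.0768), by adjusted p, which ran from 0.000359 to 0.0768 over the alternatives. Adjusted over the list alone, the counts were 22, 19 and 7. Of the lymphocyte list 1 gene was measured, Ptprc, the pan-leukocyte antigen CD45, at 0.405 ± 0.0857 against 1.58 ± 0.456 TPM (log2 fold change 0.87). Ptprc lost its call after quantile normalization (0.0938), by adjusted p, which ran from 0.000363 to 0.0938 over the alternatives. The camera test passed with the preset correlation for the interferon list (adjusted p = 6.87e-17), the macrophage list (adjusted p = 2.21e-13) and the neutrophil and mast cell list (adjusted p = 0.017). With an estimated correlation these gave adjusted p = 0.21, adjusted p = 0.15 and adjusted p = 0.31. The neutrophil and mast cell call was lost with no filter (0.107) and with a pseudocount of 5 (0.123), by adjusted p, which ran from 0.00191 to 0.123 over the alternatives.

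Matrix and connective tissue genes were also higher. In the extracellular matrix and fibrosis list 30 of 32 genes were higher and none lower (31 adjusted over the list alone, 28 after trimmed-mean rescaling), with a median log2 fold change of 1.30. Timp1, an inhibitor of matrix metalloproteinases, rose from 0.706 ± 0.192 to 8.64 ± 0.715 TPM, Postn from 5.64 ± 2.92 to 30.9 ± 2.91 TPM, and the collagens Col5a2 and Col14a1 by 1.44 and 1.46 on the log2 scale. All 16 genes of fibro-adipogenic progenitors and fibroblasts were higher (16 adjusted over the list alone, 12 after trimmed-mean rescaling; median 1.07), among them Ly6a, from 76.4 ± 12.2 to 291 ± 62.7 TPM, and Cd34, from 16.3 ± 2.16 to 53.2 ± 3.13 TPM. Both lists passed camera with the preset correlation (adjusted p = 4.02e-12 and adjusted p = 1.22e-06) and neither did with an estimated one (adjusted p = 0.21 for both). In the tendon list 3 of 7 genes were higher and 1 lower, on both scales and adjusted over the list alone. Scx, a transcription factor of tendon cells, rose from 3.67 ± 1.25 to 30.05 ± 10.6 TPM and Thbs4 from 21.6 ± 4.20 to 104 ± 22.8 TPM, while Chad fell by 0.62 on the log2 scale. Chad lost its call with no filter (0.147), with a pseudocount of 5 (0.059), on the nuclear-only scale (0.0614), without wild-type library 1 (0.2), without wild-type library 2 (0.0536), without knockout library 1 (0.112), without knockout library 3 (0.132) and without both wild-type library 2 and knockout library 1 (0.0968), by adjusted p, which ran from 0.0198 to 0.2 over the alternatives. The tendon list did not pass camera (adjusted p = 0.77).

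Part of the genes of mitochondrial fuel oxidation were lower in the knockout. Of 28 genes for fatty acid uptake and oxidation, 16 were lower and 1 higher (17 and 1 adjusted over the list alone), and after trimmed-mean rescaling 25 were lower and none higher. The median log2 fold change was -0.50. Besides Pdk4, the fatty acid binding protein Fabp3 fell from 3545 ± 891 to 1763 ± 200.2 TPM, Etfdh, which passes electrons from fatty acid oxidation to the respiratory chain, from 191 ± 20.04 to 100.1 ± 11.6 TPM, and the carnitine carrier Slc25a20 from 113 ± 9.31 to 67.7 ± 1.76 TPM. Of 45 nuclear genes for oxidative phosphorylation, 11 were lower and none higher on the deposited scale, with a median of -0.30. Adjusted over the list alone, none passed. After trimmed-mean rescaling 43 were lower, and without wild-type library 2 and knockout library 1 together none was. Ndufs1 of complex I fell by 0.61, Cox7a1 of complex IV by 0.60, Uqcrc1 of complex III by 0.53 and Atp5a1 of the ATP synthase by 0.52 on the log2 scale. Ndufs1 lost its call without both wild-type library 2 and knockout library 1 (0.106), by adjusted p, which ran from 0.00325 to 0.106 over the alternatives. Cox7a1 lost its call with no filter (0.0532), without wild-type library 2 (0.0548), without knockout library 1 (0.0524), without knockout library 3 (0.0652) and without both wild-type library 2 and knockout library 1 (0.118), by adjusted p, which ran from 0.00253 to 0.118 over the alternatives. Uqcrc1 lost its call without knockout library 1 (0.0646), without knockout library 3 (0.0524) and without both wild-type library 2 and knockout library 1 (0.116), by adjusted p, which ran from 0.00246 to 0.116 over the alternatives. Atp5a1 lost its call without wild-type library 2 (0.0546), without knockout library 1 (0.0701), without knockout library 3 (0.0664) and without both wild-type library 2 and knockout library 1 (0.135), by adjusted p, which ran from 0.00221 to 0.135 over the alternatives. Both lists lay lower than other genes in the camera test with the preset correlation (adjusted p = 8.76e-26 and adjusted p = 2.97e-26), and neither passed with an estimated correlation (adjusted p = 0.15 and adjusted p = 0.31). None of the 13 mitochondrially encoded transcripts passed limma on either scale or adjusted over the list alone. Their median was -0.17, with mt-Co1 at 64731 ± 3989 against 56254 ± 3333 TPM, and the list lay lower than other genes in camera (adjusted p = 1.41e-05), without passing at the estimated correlation (adjusted p = 0.34). That call was lost, and the direction turned, after quantile normalization (adjusted p = 0.855; range over the alternatives 4.7e-12 to 0.855). In the glycolysis list 1 of 18 genes was higher, Pgm2 (log2 fold change 0.45), and none adjusted over the list alone. Pgm2 lost its call after quantile normalization (0.938), after trimmed-mean rescaling (0.325), with no filter (0.0805), on the nuclear-only scale (0.142), without wild-type library 2 (0.123), without wild-type library 3 (0.0626), without knockout library 1 (0.125), without knockout library 2 (0.0547) and without both wild-type library 2 and knockout library 1 (0.289), by adjusted p, which ran from 0.0295 to 0.938 over the alternatives. After trimmed-mean rescaling 4 were lower. That list's median of 0.05 and mean of 0.06 were above 0 while camera placed it below other genes (adjusted p = 0.011, and adjusted p = 0.72 with an estimated correlation). The glycolysis call was lost after quantile normalization (0.361), with no filter (0.0572), without wild-type library 2 (0.0515), without knockout library 3 (0.114) and without both wild-type library 2 and knockout library 1 (0.164), by adjusted p, which ran from 0.000442 to 0.361 over the alternatives.

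**Figure D2:**
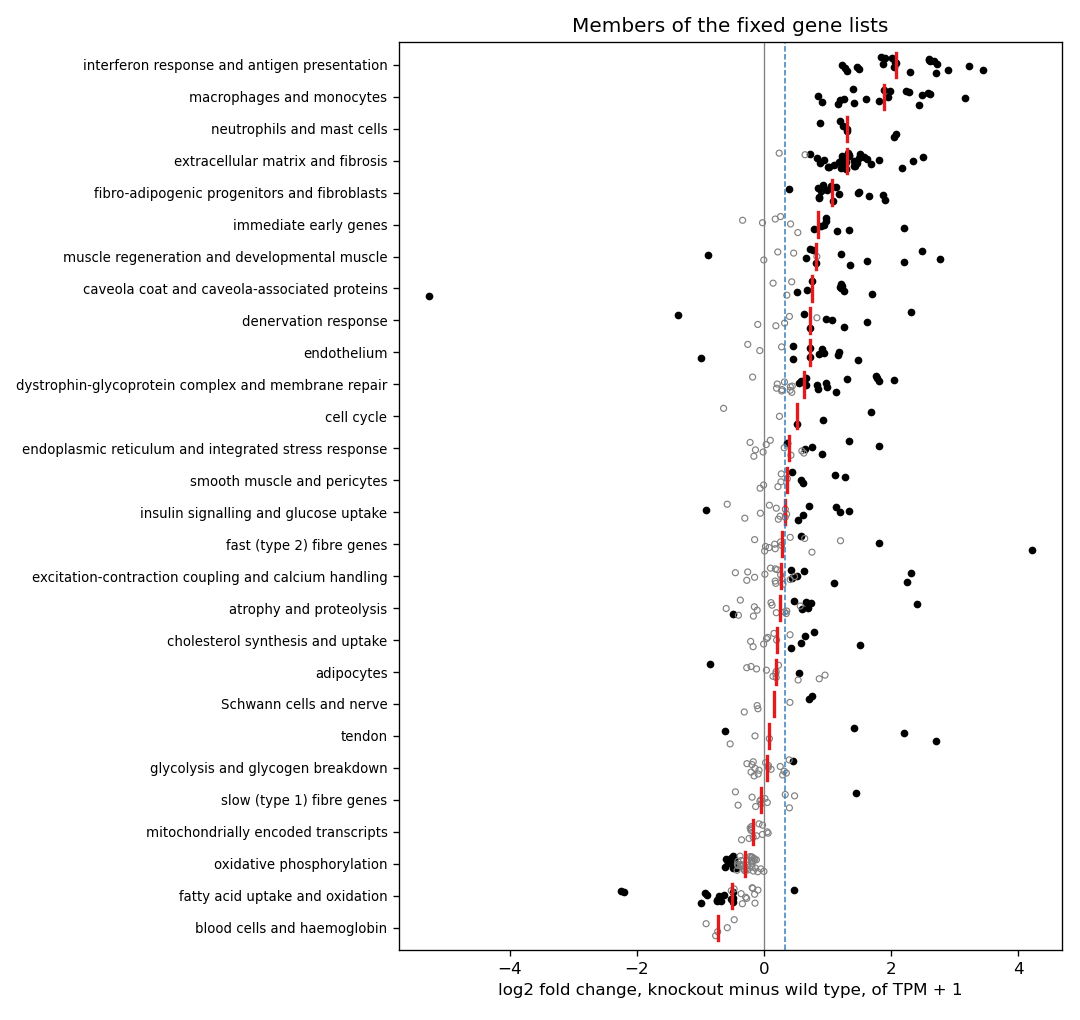
Log2 fold change, knockout minus wild type, on the TPM + 1 scale for each measured member of the 28 lists with at least 5 measured members; filled points passed limma, open grey points did not, red bars are list medians and the dashed blue line is the median of all genes at 0.33. The interferon and macrophage lists lie farthest to the right, with medians of 2.07 and 1.90, and fatty acid oxidation and haemoglobin lie to the left of 0, with medians of -0.50 and -0.73.

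Few contractile genes passed the test. Of 13 slow fibre genes 1 was higher, Ankrd2, a stretch-responsive ankyrin repeat protein (696 ± 163 against 1951 ± 656 TPM), and none lower (1 adjusted over the list alone; 1 higher and 1 lower after trimmed-mean rescaling). The median of this list was -0.04, its mean 0.11, and camera placed it below other genes (adjusted p = 0.023, and adjusted p = 0.72 with an estimated correlation). The slow fibre call was lost after quantile normalization (0.855), with the 10 TPM filter (0.195), without wild-type library 3 (0.129) and without knockout library 2 (0.172), by adjusted p, which ran from 0.00196 to 0.855 over the alternatives. Myh7, the heavy chain of type 1 fibres, stood at 2193 ± 501 TPM in wild type and 2891 ± 604 TPM in knockout (adjusted p = 0.15), and Tnnt1 at 2740 ± 481 and 2643 ± 282 TPM (adjusted p = 0.85). Myh7 passed as higher without knockout library 2 (0.0373), by adjusted p, which ran from 0.0373 to 0.893 over the alternatives. Of 15 fast fibre genes 3 were higher, Myh4, Mylk2 and Actn3 (2 adjusted over the list alone, 1 after trimmed-mean rescaling). The list's median was 0.28 and camera did not pass (adjusted p = 0.77). It passed as higher without both wild-type library 2 and knockout library 1 (adjusted p = 0.00876, range over the alternatives 0.00876 to 0.934). It did not pass there with an estimated correlation (adjusted p = 0.403). The mean log2(TPM + 1) of this list was highest of the wild type in wild-type library 2 (9.72). Of the knockout it was lowest in knockout library 1 (9.60). Leaving out both favours a higher result in advance, so that call is no evidence of a rise. Actn3 lay at 9.67, 104 and 22.8 TPM in the wild-type libraries and at 70.7, 147 and 109 TPM in the knockout libraries, so that the groups overlapped. Actn3 lost its call after quantile normalization (0.167), after trimmed-mean rescaling (0.188), with no filter (0.147), on the nuclear-only scale (0.118), without wild-type library 1 (0.0827), without wild-type library 3 (0.109), without knockout library 1 (0.0502) and without knockout library 2 (0.053), by adjusted p, which ran from 9.32e-05 to 0.188 over the alternatives. Mylk2 lost its call after quantile normalization (0.0779), after trimmed-mean rescaling (0.211), without wild-type library 2 (0.0502) and without both wild-type library 2 and knockout library 1 (0.0804), by adjusted p, which ran from 0.00692 to 0.211 over the alternatives. Wild-type library 2 was the wild-type library with most Myh4. Tnnt3 was at 7892 ± 462 and 8938 ± 809 TPM (adjusted p = 0.37), a difference that turned negative after trimmed-mean rescaling.

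**Figure D3:**
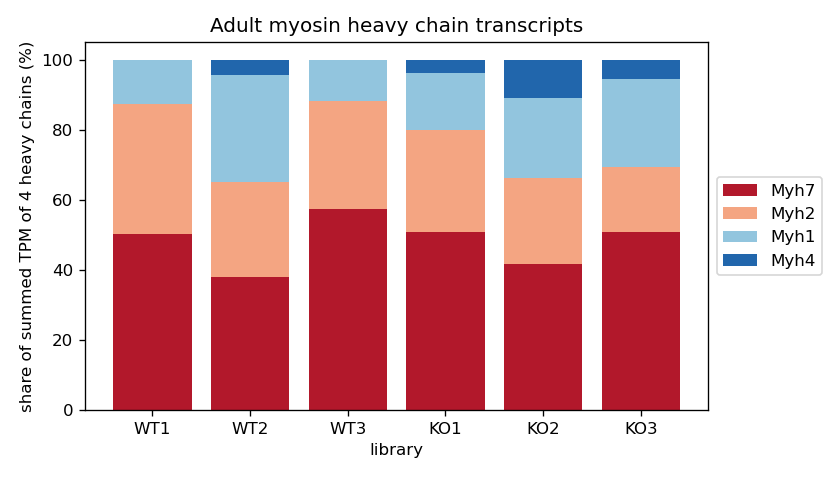
Stacked bars give, for each of the 6 libraries, the share in percent of the summed TPM of the 4 adult myosin heavy chain genes. Myh7 took at least 38.0% in every library, and Myh4 took 0.148, 4.33 and 0.0896% in the wild-type libraries and up to 10.997% in the knockout libraries.

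Genes of regeneration and membrane repair were partly higher, against 4016 of 11056 among all tested genes. The excitation-contraction coupling list stayed below that share on the deposited scale. In the regeneration and developmental muscle list 10 of 15 genes were higher and 1 lower (12 and 1 adjusted over the list alone, 8 and 1 after trimmed-mean rescaling). Myod1 and Myog, myogenic transcription factors, rose from 1.59 ± 0.394 to 11.1 ± 2.52 TPM and from 1.43 ± 0.274 to 6.83 ± 2.76 TPM, Mybph by 2.77 and Ankrd1 by 2.49 on the log2 scale. In the dystrophin complex and membrane repair list 14 of 24 genes were higher and none lower (16 adjusted over the list alone; 10 higher and 1 lower after trimmed-mean rescaling). The members named by the rule belong to the repair side of that list, with Anxa1 up by 1.81, Anxa2 by 2.05, Myof by 1.76 and Ahnak by 1.77. Both lists passed camera with the preset correlation (adjusted p = 0.036 and adjusted p = 0.0024), and both gave adjusted p = 0.72 with an estimated correlation. The regeneration call was lost with the 10 TPM filter (0.0972), with a pseudocount of 0.1 (0.0572), with a pseudocount of 5 (0.103), without wild-type library 2 (0.0515) and without wild-type library 3 (0.0675), by adjusted p, which ran from 0.00175 to 0.103 over the alternatives. In the denervation list 7 of 13 genes were higher and 1 lower, also adjusted over the list alone (6 and 2 after trimmed-mean rescaling), with Runx1 up by 1.07 and Dach2 down from 6.30 ± 0.398 to 1.86 ± 0.184 TPM (camera adjusted p = 0.37). In the excitation-contraction coupling list 7 of 22 genes were higher (6 adjusted over the list alone; 4 higher and 1 lower after trimmed-mean rescaling; camera adjusted p = 0.96). Sln, the sarcolipin inhibitor of the calcium pump, rose from 62.9 ± 18.5 to 332 ± 145 TPM and the calcium channel subunit Cacng1 from 32.1 ± 4.46 to 156.5 ± 26.9 TPM.

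Markers of other cell types were higher in part, against 4016 of 11056 among all tested genes on the deposited scale. Of 14 endothelial genes 10 were higher and 1 lower, also adjusted over the list alone (8 and 3 after trimmed-mean rescaling; camera adjusted p = 0.22), with Pecam1 up from 28.1 ± 0.829 to 80.1 ± 10.3 TPM. Camera passed for the endothelial list after quantile normalization (0.0392), with no filter (0.0472) and with the 10 TPM filter (0.0439), by adjusted p, which ran from 0.0392 to 0.344 over the alternatives. None of these passed with an estimated correlation (adjusted p = 0.224 to adjusted p = 0.588). Of 11 smooth muscle and pericyte genes 5 were higher, also adjusted over the list alone (2 after trimmed-mean rescaling; camera adjusted p = 0.37), led by Mcam (1.12) and Cspg4 (1.28). Pdgfrb (0.58) lost its call after quantile normalization (0.32) and after trimmed-mean rescaling (0.16), by limma adjusted p. Smtn (0.61) lost its call after quantile normalization (0.0694), after trimmed-mean rescaling (0.0854) and without wild-type library 2 (0.0544). The Smtn call was also lost without both wild-type library 2 and knockout library 1 (0.116). Camera passed for the smooth muscle list with no filter (0.0163), by adjusted p, which ran from 0.0163 to 0.744 over the alternatives. It did not pass there with an estimated correlation (adjusted p = 0.367). Of 6 Schwann cell and nerve genes 2 were higher, Cnp and L1cam, also adjusted over the list alone (1 higher and 2 lower after trimmed-mean rescaling; camera adjusted p = 0.52). Cnp lost its call after quantile normalization (0.168) and after trimmed-mean rescaling (0.0519), by adjusted p, which ran from 0.00257 to 0.168 over the alternatives. L1cam lost its call after quantile normalization (0.0977), by adjusted p, which ran from 0.00145 to 0.0977 over the alternatives. Camera placed the Schwann cell list below other genes with no filter (0.0427), by adjusted p, which ran from 0.0427 to 0.974 over the alternatives. It did not pass there with an estimated correlation (adjusted p = 0.513). Of 14 adipocyte genes Cebpa was higher and Dgat2 lower, also adjusted over the list alone (1 lower after trimmed-mean rescaling). Cebpa lost its call after quantile normalization (0.511), after trimmed-mean rescaling (0.139), with no filter (0.0622), on the nuclear-only scale (0.0517), without wild-type library 1 (0.0703), without knockout library 1 (0.0734), without knockout library 3 (0.0852) and without both wild-type library 2 and knockout library 1 (0.0909), by adjusted p, which ran from 0.00383 to 0.511 over the alternatives. The adipocyte median was 0.19, while camera placed the list below other genes (adjusted p = 0.038, and adjusted p = 0.72 with an estimated correlation). The adipocyte call was lost after quantile normalization (0.306), after trimmed-mean rescaling (0.208), with the 10 TPM filter (0.0662), on the nuclear-only scale (0.0748), without wild-type library 2 (0.249), without knockout library 2 (0.993) and without both wild-type library 2 and knockout library 1 (0.0872), by adjusted p, which ran from 0.0063 to 0.993 over the alternatives. None of the 5 haemoglobin and erythroid genes passed limma, on either scale or adjusted over the list alone. Their median was -0.73, with Hbb-bs at 494 ± 185 and 397 ± 337.5 TPM, and camera placed the list below other genes (adjusted p = 0.00041, and adjusted p = 0.47 with an estimated correlation). The haemoglobin call was lost after quantile normalization (0.207), after trimmed-mean rescaling (0.0798) and without both wild-type library 2 and knockout library 1 (0.191), by adjusted p, which ran from 2.1e-11 to 0.207 over the alternatives. Hbb-bs passed as lower without knockout library 3 (0.0108), by adjusted p, which ran from 0.0108 to 0.948 over the alternatives. Its log2 fold change of -0.58 became -0.04 without knockout library 1.

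Stress and growth lists held a minority or a small majority of higher genes, where 4016 of all 11056 tested genes were higher. None of these lists passed camera on the deposited scale with the 6 libraries. Of 14 immediate early genes 8 were higher, also adjusted over the list alone (6 after trimmed-mean rescaling; adjusted p = 0.19), with Egr1 up by 2.21 and Junb by 1.34 on the log2 scale. Camera passed for immediate early genes after quantile normalization (0.0299), without wild-type library 2 (0.0419), without knockout library 1 (0.00735) and without both wild-type library 2 and knockout library 1 (0.000502), by adjusted p, which ran from 0.000502 to 0.454 over the alternatives. None of these passed with an estimated correlation (adjusted p = 0.672 to adjusted p = 0.721). Of 5 cell cycle genes 3 were higher, also adjusted over the list alone (2 after trimmed-mean rescaling; adjusted p = 0.65), led by Rrm2 (1.68). Of 16 genes of endoplasmic reticulum and integrated stress 6 were higher, also adjusted over the list alone (4 higher and 1 lower after trimmed-mean rescaling; adjusted p = 0.96), led by Atf3 (1.82). Of 20 atrophy and proteolysis genes 6 were higher and 1 lower, also adjusted over the list alone (1 and 4 after trimmed-mean rescaling; adjusted p = 0.10). Camera placed the atrophy list below other genes without wild-type library 1 (0.0197), by adjusted p, which ran from 0.0197 to 0.855 over the alternatives. It did not pass there with an estimated correlation (adjusted p = 0.632). The member of that list with the smallest p, Mt2, encodes a metallothionein and lay at 59.0 ± 34.6 against 330.4 ± 190.4 TPM. Of 17 insulin signalling genes 6 were higher and 1 lower, also adjusted over the list alone (4 and 4 after trimmed-mean rescaling; adjusted p = 0.74). Slc2a1 and Tbc1d1 rose by 1.20 and 1.34, and Tbc1d4, a regulator of glucose transporter traffic, fell by 0.91. Of 13 cholesterol genes 5 were higher, also adjusted over the list alone (3 higher and 2 lower after trimmed-mean rescaling; adjusted p = 0.74), among them Srebf2 (0.79). Srebf2 lost its call after quantile normalization (0.0545), by adjusted p, which ran from 0.00116 to 0.0545 over the alternatives. In the fast fibre, excitation-contraction coupling, Schwann cell, tendon, atrophy, stress, insulin and cholesterol lists the median was above 0 while camera, without passing, placed the list below other genes. In all, 14 of 28 lists passed camera with the preset correlation and none with an estimated correlation. With the estimated correlation the fatty acid list passed without wild-type library 3 (adjusted p = 0.0278) and on the nuclear-only scale (adjusted p = 0.0398), where the macrophage list also passed (adjusted p = 0.0371).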

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

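The nuclear-only scale and leaving out both libraries in doubt were chosen after seeing the data; the other alternatives were planned. Both labelled knockout comparisons gave 4339 passing genes, 4016 higher and 323 lower. Fits over all 12 samples or over distinct libraries reduce to the same 6 libraries, and the alternatives for counts do not apply to TPM. The total became 2823 after quantile normalization (1373 higher, 1450 lower), 1839 with a filter of 10 TPM (1616 higher) and 912 with an absolute log2 fold change of at least 1 (861 higher, 51 lower). Fewer genes can pass under those last settings. Trimmed-mean rescaling gave 1717 higher and 1302 lower, and the nuclear-only scale 2850 higher and 777 lower. Leaving out each library gave totals from 2648 to 4458, with 2379 to 4150 higher and 219 to 346 lower. The total was 2784 without wild-type library 2, 2648 without knockout library 1 and 2724 without knockout library 3. Without both libraries in doubt it was 1886 (1673 higher, 213 lower). List members higher were then 20 for interferon, 14 for macrophages, 3 for neutrophils and mast cells, 28 for matrix and 13 for fibroblasts. None was for lymphocytes, and 12 fatty acid genes were lower. Fewer genes met the filter in that fit (10453), so a member not counted may not have been tested. A wild-type library left out also removes Cavin1 from the test, since fewer than 3 libraries then reach 1 TPM. Correlations of the deviations of same-numbered libraries were 0.03, -0.01 and 0.04, and no wild-type library correlated best with its own number. Pairing stays open for fibre genes. The replicate block gave 4373 genes (4047 higher, 326 lower).

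Lists passing camera with the preset correlation numbered 11 to 16 over the alternatives, against 14, and with an estimated correlation 0, except 2 on the nuclear-only scale and 1 without wild-type library 3. Of 110 named genes 77 kept direction and call under every alternative that tested them, and of 28 lists 9 did; the calls of single lists that changed stand beside each list in the results. Genes whose sign turned were not called with the 6 libraries: Tnnt3 (0.18) became -0.183 after trimmed-mean rescaling and -0.0242 on the nuclear-only scale, Hbb-bs (-0.58) became 0.137 without both libraries in doubt and ran from -1.24 to -0.0439 with single libraries left out, passing as lower without knockout library 3 (adjusted p = 0.0108), and Tnnt1 (-0.04) ranged from -0.146 to 0.0929 with single libraries left out, and was above 0 without wild-type library 3 or knockout library 2.

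The direction of the camera test turned for lists that had not passed and, under quantile normalization, for the mitochondrially encoded list, which had and then no longer passed (adjusted p = 0.855; range over the alternatives 4.7e-12 to 0.855). The fast fibre list, not passing otherwise, passed in the upward direction without both libraries in doubt (adjusted p = 0.00876, and adjusted p = 0.403 with an estimated correlation). Leaving them out removes the highest wild-type and the lowest knockout score of this list, which favours that direction in advance. Values are list medians relative to all genes, whose sign can differ from that of the test. The cause was not tested. Cholesterol genes (-0.125) gave 0.0229 with no filter. Endoplasmic reticulum stress genes (0.0669) gave 0.141 with quantile normalization, 0.106 with trimmed-mean rescaling, 0.145 with no filter, 0.0744 with the 10 TPM filter, 0.0669 with the replicate block, 0.106 with the nuclear-only scale and 0.0253 with both libraries in doubt left out, and 0.014 to 0.203 with single libraries left out, turned without wild-type library 2 or wild-type library 3 or knockout library 1 or knockout library 2. Excitation-contraction coupling genes (-0.0508) gave 0.114 with quantile normalization, 0.0976 with no filter, -0.0116 with the 10 TPM filter, 0.0693 with pseudocount 5 and -0.0104 with both libraries in doubt left out, and -0.0982 to -0.00793 with single libraries left out, turned without wild-type library 2 or knockout library 1 or knockout library 2 or knockout library 3. Fast fibre genes (-0.0477) gave 0.172 with quantile normalization, 0.101 with no filter, -0.0201 with the 10 TPM filter, -0.0477 with the replicate block and 0.208 with both libraries in doubt left out, and -0.144 to 0.11 with single libraries left out, turned without wild-type library 2 or knockout library 1. Insulin signalling genes (0.00989) gave 0.0116 with quantile normalization, 0.158 with no filter and 0.0152 with both libraries in doubt left out. Mitochondrially encoded genes (-0.495) gave 0.0414 with quantile normalization. Tendon genes (-0.239) gave -0.186 with quantile normalization, -0.281 with trimmed-mean rescaling and -0.0797 with both libraries in doubt left out, and -0.507 to -0.0359 with single libraries left out, turned without wild-type library 1 or knockout library 1.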

Other observations

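The tests in this part, those on other splits of the samples included, were all written down after the results they bear on were seen, and the genes of the next paragraph were chosen after their values were seen.

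Genes of the circadian clock differed between the groups in opposite directions. Of 12 clock output and repressor genes known to run roughly opposite to the activator gene Arntl (Bmal1), 12 were higher in the knockout by limma (9 after trimmed-mean rescaling), and of 5 genes in phase with Arntl 2 were lower (5 after trimmed-mean rescaling). Dbp rose from 2.82 ± 0.838 to 19.9 ± 7.53 TPM, Per3 from 0.818 ± 0.056 to 5.27 ± 0.561 TPM, Tef from 37.4 ± 1.29 to 102 ± 14.1 TPM and Nr1d1 from 11.3 ± 2.498 to 40.2 ± 12.97 TPM (SD, n = 3 each). Arntl fell from 19.6 ± 1.28 to 9.54 ± 2.05 TPM and Nfil3 from 20.2 ± 3.62 to 9.94 ± 3.49 TPM. Per2 and Per3 were under 1 TPM in every wild-type library, so being higher was a condition for testing them.

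For the clock genes, the scale of the TPM values alone is argued against: it moves all genes of a library one way, whereas after trimmed-mean rescaling 14 of the 17 genes passed limma, 9 higher in one arm and 5 lower in the other. A shift of clock phase between the groups stays open as a hypothesis, untested here because the genes were chosen after their values were seen. Whether such a shift came with the genotype or with the hour of collection is open too, since the labels used here give no hours.

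The equal values under both muscle names leave the tissue unknown. A mainly type 2B muscle is argued against as the origin of all 6 libraries, since Myh4 took at most 10.997% of the adult heavy chain TPM. A muscle rich in type 1 fibres is consistent with Myh7 taking at least 38.0% in every library. Mixed tissue stays open, and no library is assigned to a muscle here.

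For the higher macrophage genes, a lower share of fibre RNA alone would raise all other cell types alike. Instead, the macrophage score (the mean log2(TPM + 1) of the list) rose by 1.39 (SE 0.068) beyond the smooth muscle score on the log2 scale. The scale of the TPM values is argued against by the 18 macrophage genes that stayed higher of 18 after trimmed-mean rescaling. More blood in the knockout muscle is argued against as the whole source of the macrophage change, since it would raise the haemoglobin and erythroid score as well. That score changed by -2.54 (SE 0.689) relative to the macrophage score, a difference lower in every knockout library than in any wild-type library. Most of it is the macrophage rise itself, 1.86, against a change of -0.688 (SE 0.710) in the haemoglobin and erythroid score. The contrast was chosen after that score's own change had left more blood open. The haemoglobin and erythroid score itself lay at 5.01 and 5.78 in knockout libraries 1 and 2, below the lowest wild-type library (6.19), and at 7.27 in knockout library 3, above the highest (7.004). The contrasts with the smooth muscle and haemoglobin scores were made for the macrophage list alone. A lower share of fibre RNA and more blood were not tested for the interferon, matrix and fibroblast lists. More immune and connective tissue cells, or more of these transcripts per cell, stay open as hypotheses on the biological side, since single cells were not measured.

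The 6 libraries allow 10 splits of 3 against 3, too few for a share under 0.05. The real split gave 4339 genes and the highest other split gave 0, so 1 of 10 splits reached the real count. Every other split puts both genotypes in each group, so a genotype difference widens the spread within groups and lowers the count. The gene counts therefore cannot decide about chance. For lists passing camera with the preset correlation, the real split gave 14 and the other splits 7 to 12, and 1 of 10 reached the real count. Camera with the preset correlation thus passed many lists in splits that mix the genotypes too.

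Wild-type library 2 held 104 TPM of Actn3 and 462 TPM of Pvalb, against 9.67 and 22.8 TPM and 76.8 and 141 TPM in wild-type libraries 1 and 3. Knockout library 2 also held the most of its group, with 147 TPM of Actn3 and 730 TPM of Pvalb. The fast fibre score was highest in library 2 of both genotypes (9.72 and 9.998), and the slow fibre score was lowest there (9.24 and 9.42). Myh1 was highest in wild-type library 2 but in knockout library 3. Whether the numbers pair the samples for these genes was not tested. The summed TPM of 22 liver transcripts was 118 in knockout library 1, with 15.1 TPM of Alb, and 8.44 to 31.4 in the other 5 libraries. Of 45 tested genes within 1 Mb of Cavin1, 21 were higher and 0 lower by limma, with a median log2 fold change of 0.41, against 0.33 for all genes. Among all 11056 tested genes 4016 were higher and 323 lower.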
